A study of Danio rerio with 13 samples.

How the data were processed

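Zebrafish embryos of the Tübingen strain were profiled in 2 ways, per the labels. In ssDRIP-seq, RNA:DNA hybrids in restriction-digested genomic DNA were immunoprecipitated with the S9.6 antibody and the DNA strand was sequenced with its orientation, at the 256-cell, sphere and shield stages with 2 biological replicates each. In small RNA sequencing, 1 library each was made from mature oocytes (egg), 1-cell, 256-cell, sphere, shield and 24 hpf (hours post fertilisation) embryos. Per the labels' protocols, the small RNA was treated with T4 PNK and an AlkB protein mix, which remove end groups and base methylations that block cloning, and was size-selected before sequencing. An ssDRIP control pre-treated with RNase H was listed for the shield stage and was not analysed here, so no background from a hybrid-depleted sample stands beside the values.

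The deposited sense and antisense tables hold whole counts per annotated feature (37129 features each), and these counts were the input of every ssDRIP test. The authors also deposited normalized tables whose unit is named here as signal. Each signal value was its count times 1 constant per column (relative spread 1.1e-09), and these constants served as an alternative scaling. The deposited small RNA table holds RPM, reads scaled to the depth of the library, for 81680 tRNA-derived fragments of 18 to 44 nt. Every RPM value was a whole multiple of the column's smallest step within a tolerance of 0.01, so whole reads could be recovered. The RPM columns sum to 43632 to 83539, so the denominator included reads outside the listed fragments, and its definition is not given in the sources used here. A set of 507 emptied lines of that table was not used here. Per the submitters' processing notes, cutadapt, Trimmomatic, Bowtie2, SAMtools, Picard, deepTools, MACS2 and DESeq2 were used for ssDRIP-seq with the builds GRCz10 and GRCz11, with no role or order given. For small RNA, the same notes name FastQC 0.11.8, cutadapt 1.16, Bowtie2 2.3.4.1, featureCounts and GRCz11. The rule for reads that map to several places is not given in the sources used here, which matters for tRNA genes and the mir430 copies. The terms sense and antisense are those of the deposited tables, and which physical strand they denote is not given in the sources used here. No coordinates are printed, since the build behind the feature table is not stated.

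Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Features were filtered with filterByExpr, scaled by TMM, and fitted with the quasi-likelihood F-test (two-sided) on stage, with all 6 libraries in 1 fit per strand. A feature was called at a Benjamini-Hochberg FDR of 0.05 over all features tested, which were 31891 sense, 27579 antisense and 33163 for the sense to antisense ratio. For that ratio, the library size of both strand columns was their sum, each library was a term of the model, and the change of the ratio from the 256-cell stage to shield was tested as an interaction. Log2 changes are given with the standard error (SE) of the fit, levels in CPM (counts scaled to the library size times its TMM factor, prior count 2 on the log scale), and shares with the SD over 2 libraries. The common dispersion was 0.0141 for sense and 0.0111 for antisense. P-values measure the spread between these libraries. A ratio against a stage with 0 counts in both libraries was bounded with a floor of 3 counts over the group and written "at least". Intervals and floors cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

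Gene lists were fixed before the data were examined: 10 tRNA families known for 5′ fragments (Gly-GCC, Gly-CCC, Glu-CTC, Glu-TTC, Lys-CTT, Lys-TTT, Val-CAC, Val-AAC, Asp-GTC and His-GTG), all nuclear tRNA genes, small nuclear and ribosomal RNA, mir430, mitochondrial, ribosomal protein, histone, early zygotic, maternal, gastrula, late tissue and housekeeping genes. The mitochondrial list matched only mt-rnr1 and mt-rnr2, fewer than the smallest list tested (5), and the small nuclear and ribosomal RNA list matched 0 tested features by name, while 1 feature each of these classes was tested in the sense counts under another name. The 37 genes of the mitochondrial genome were therefore added as a list after seeing the data. The ribosomal protein pattern also caught the S6 kinases rps6ka4, rps6ka3b and rps6kb1a. Lists were tested with camera (preset correlation 0.01), with an estimated correlation and with fry, which tests whether a list's genes move on balance 1 way without comparing them with other genes. Camera compares a list with all other tested features, among them the nuclear tRNA genes. The 110 list tests were adjusted together.

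The tests, the alternatives and the rule for named genes were also set before the data were examined. In each comparison the rule took, among called features that changed the same way in all 4 pairs of libraries, the 12 largest changes per direction and up to 6 called members per list. For the strand ratio it took the 6 largest per direction. Part of the features these rules took is not reported here. For fragments it took the 15 largest families, the families of the 5′ list, the 10 most abundant fragments and the 5 largest rises and falls among families of at least 100 RPM. Any other feature named was chosen after its values were seen. Sums over isoacceptor families and over the mir430 cluster, the fits without mitochondrial genes, the scaling of tRNA genes on the library size of nuclear counts and the test of 2 small RNA libraries against each other were also added after seeing the data.

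Fragment families were compared as log2(RPM + 1). With 1 library per stage no test of stage is possible, so changes of 2-fold or more are counted as values. An exact binomial test of the recovered reads was added, which compares those libraries, not the conditions. Family values carry exact Poisson intervals and class shares Wilson intervals, both at 95%. Across 54 families, 5′ fragments of at least 30 nt were correlated with the mean log2 CPM of the family's genes by Pearson's r and Spearman's rho with permutation tests (two-sided, 100000 resamples) in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

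Alternatives were library size scaling, DESeq2 1.42.0 size factors and Wald test, the authors' scaling, no filter, a stricter filter (10 counts), fits on only the stages compared, a replicate block, the library size of both strands together, separate TMM factors per strand column, and each replicate left out. For fragments they were pseudocounts of 0.1 and 10 RPM, a filter of 1 RPM and shares of the summed fragments. The replicate numbers of the titles showed no clear pairing: correlations of the replicate differences between stages ran from -0.0297 to 0.0922. With 2 libraries per group no other splits were counted. When tested on simulated data of the same design, the stage test recovered 53% of 2-fold and 85% of 4-fold changes with 5 false of 143 calls. The strand test recovered 43% and 78% with 5 false of 126. The simulated changes were few and balanced in direction, with no fall of the mitochondrial share. The rate of false calls therefore need not carry over to these data.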

Results

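R-loops, the RNA:DNA hybrids formed when RNA pairs with genomic DNA, were mapped by ssDRIP-seq in zebrafish embryos at the 256-cell, sphere and shield stages, with 2 biological replicates per stage. The 256-cell stage precedes the main wave of zygotic transcription, sphere follows it, and shield marks early gastrulation. Total sense counts were 5979021 and 8787916 at the 256-cell stage, 7838104 and 8724689 at sphere, and 10672396 and 10081495 at shield (replicates 1 and 2). Total antisense counts were 4903769 and 7411069, 8399653 and 9429596, and 11382468 and 10900968 in the same order. Replicates correlated at r between 0.968 and 0.989 across features (log2 CPM), and their counts differed by 2.63 to 3.95 times the variance of pure counting. Fragments of tRNA were sequenced in 6 small RNA libraries, 1 per stage, with 819372 reads in listed fragments in the egg, 651410 at the 1-cell, 615974 at the 256-cell, 1017464 at the sphere, 1080268 at the shield stage and 1005838 at 24 hpf.

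The mitochondrial genome, which encodes the core subunits of the respiratory chain, took 33.0% ± 1.02 of the sense counts at the 256-cell stage, 4.39% ± 0.833 at sphere and 1.83% ± 0.484 at shield (SD, n = 2). Its share of the antisense counts was 6.14% ± 0.135, 0.446% ± 0.0395 and 0.209% ± 0.0562. The mir430 cluster, microRNA genes transcribed at genome activation whose products clear maternal mRNA, held 0.212% ± 0.0387, 0.611% ± 0.0287 and 0.247% ± 0.00260 of the nuclear sense counts. Nuclear tRNA genes held 2.80% ± 0.592, 2.65% ± 0.0991 and 1.85% ± 0.0299 of them. Because the mitochondrial share shrank, the scaling of the libraries matters: with library size alone, the median of all sense features shifted by 0.58 (sphere) and 0.60 (shield) on the log2 scale against the 256-cell stage. The antisense median shifted by 0.18 and 0.20. As the mitochondrial share of the antisense counts was only 6.14% at the 256-cell stage, it need not be the whole source of the antisense shift, which was not tested. Relative to the sense shift, the median change from the 256-cell stage to shield was -4.82 for mitochondrial and -0.79 for nuclear tRNA genes, and the median change to sphere was 1.47 for mir430.

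**Figure D1:**
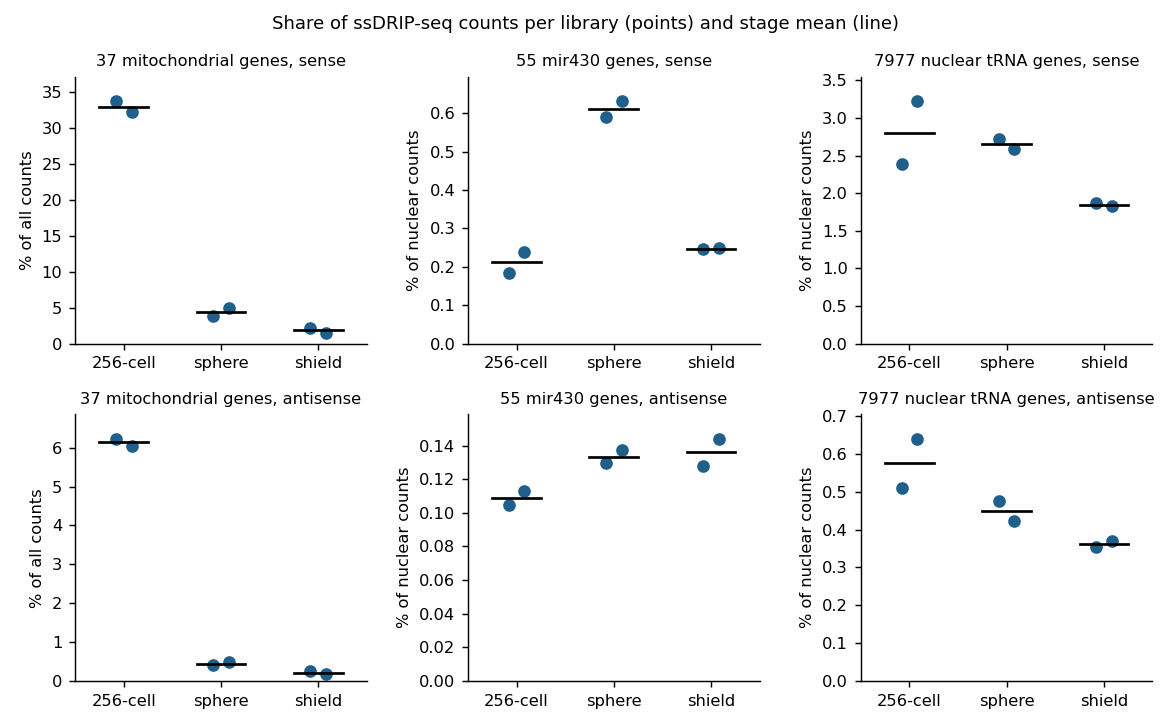
Share of the counts per library (y axes, percent) at the 256-cell, sphere and shield stages (x axes) for mitochondrial genes (of all counts) and for mir430 and nuclear tRNA genes (of nuclear counts), on the sense and antisense strands. Points are libraries and horizontal lines are stage means. The sense mitochondrial share dropped from 33.0% to 1.83%, and the sense mir430 share peaked at sphere (0.611%).

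The comparison of sphere with the 256-cell stage asks where R-loops changed as the embryo's own genome became active. In the sense counts, 49 of the 55 mir430 genes rose and 0 fell by the edgeR test (53 at unadjusted p under 0.05, 46 by DESeq2, 53 adjusted over the list alone), with a median log2 change of 1.47. The gene mir430a-15 (gene5730) rose by 1.82 ± 0.11 (SE, n = 2 per stage), from 73.5 to 261 CPM, mir430a-13 by 1.57 ± 0.12 and mir430c-16 by 1.49 ± 0.11. Summed over the cluster, counts went from 1867 ± 300.2 to 5154 ± 357 CPM (SD, n = 2), a 2.76-fold rise (adjusted p = 1.79e-09). All 37 mitochondrial genes fell, with a median of -3.51. The log2 change was -4.29 ± 0.13 for ND1, a complex I subunit, -4.54 ± 0.19 for ATP6 of the ATP synthase and -3.21 ± 0.15 for the large ribosomal RNA gene mt-rnr2. Camera gave mir430 an adjusted p = 6.11e-158, and adjusted p = 0.0555 with an estimated correlation. The mitochondrial list had adjusted p = 0.0176 with an estimated correlation.

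Nuclear tRNA genes went both ways between these stages: 52 rose and 58 fell of 5567 tested (34 and 37 by DESeq2, median -0.17, adjusted p = 0.301), and with library size alone 672 rose and 9 fell (median 0.40 against 0.58 for all features). Among them trnal-aag gene12116, a leucine tRNA gene, rose by 2.02 ± 0.25 and trnav-cac gene9050 by 1.43 ± 0.23, while trnag-ucc gene5758 fell by 1.28 and trnav-aac gene9078 fell by 1.08. In the 10 families known for 5′ fragments, 13 genes rose and 24 fell of 1745 (10 and 13 by DESeq2, 9 and 9 adjusted over the list alone). Their camera test had adjusted p = 0.00635, adjusted p = 0.662 with an estimated correlation and 0.990 without 256-cell replicate 2. Summed over isoacceptor families, Leu-AAG rose by 1.06 ± 0.14, Tyr-GTA by 0.90 ± 0.21 and Glu-TTC by 0.63 ± 0.14, and Gln-TTG fell by 0.83. In total 4 of 60 families rose and 10 fell, against 34 and 1 with library size alone. Of these, Leu-AAG, Gln-TTG, Gln-CTG and Pro-AGG were called whichever library was left out. The median tRNA change was 0.21 without 256-cell replicate 2 and -0.32 without replicate 1.

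Among protein-coding genes at sphere, ved, a homeobox repressor of the early zygotic list, rose by 2.09 ± 0.29, and the chemokine receptor cxcr2 (gene19706) by 3.19 ± 0.64. LOC110439902 (gene17078) was at least 9.60-fold higher, having no sense count at the 256-cell stage. Of the early zygotic list 1 gene rose and 1 fell (bmp4, -0.75, a call lost with library size alone) of 43 (1 and 1 by DESeq2, 2 and 1 adjusted over the list alone, adjusted p = 0.0782 by camera). Of 28 maternal genes 2 fell, the mRNA decay factor gene btg4 (-3.25 ± 0.68) and the zinc finger gene cth1 (-1.95 ± 0.46) (1 by DESeq2, 4 adjusted over the list alone, adjusted p = 0.128). The linker histone gene h1fx rose by 1.36 (1 of 16 histone genes, 1 by DESeq2, 1 adjusted over the list alone, adjusted p = 0.627). Among the 31891 sense features, 414 were higher and 808 lower (840 in all by DESeq2), against 14110 and 217 with library size alone. Without sphere replicate 1 the total was 448 and the calls of bmp4, btg4, cth1 and h1fx were lost, as they were in other fits that left out 1 sphere or 256-cell library. No gene was called in the ribosomal protein, gastrula, late tissue and housekeeping lists by edgeR or DESeq2 (0 of 84, 25, 24 and 16; 11, 3, 1 and 3 at unadjusted p under 0.05; adjusted p = 0.656, 0.411, 0.995 and 0.653 by camera). Adjusted over the list alone the counts were 0, 0, 0 and 1.

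The comparison of shield with the 256-cell stage asks how R-loops stood in the gastrula, and whether those at tRNA genes differed. With TMM scaling nuclear tRNA genes fell: 853 were lower and 31 higher of 5567 tested in the sense counts, with a median log2 change of -0.80. The glycine genes trnag-ccc gene6829 and trnag-gcc gene7161 changed by -2.43 ± 0.37 and -2.08 ± 0.31 (SE, n = 2 per stage), the lysine gene trnak-cuu gene25330 by -1.47 ± 0.22 and the glutamine gene trnaq-uug gene23592 by -1.40 ± 0.18. Against that direction, trnal-aag gene12116 rose by 1.83 ± 0.25 and the aspartate gene trnad-guc gene5748 by 1.75 ± 0.25. Adjusted over the list alone, 1100 fell and 34 rose. Camera gave adjusted p = 4.59e-16, and adjusted p = 0.351 with an estimated correlation. In the 10 families known for 5′ fragments, 397 genes fell and 12 rose of 1745 (211 and 5 by DESeq2, 648 and 14 adjusted over the list alone), with adjusted p = 9.91e-20, and adjusted p = 0.280 with an estimated correlation. Fry passed neither list, with adjusted p = 0.0869 for all nuclear tRNA genes and 0.0502 for these families. With library size alone, 347 tRNA genes were lower and 251 higher (median -0.20 against 0.60 for all features), and DESeq2 called 434 and 14. The number of lower tRNA genes was 252 without 256-cell replicate 2, 134 without shield replicate 1 and 236 without shield replicate 2.

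Summed over isoacceptor families, 39 of 60 fell and 1 rose, against 12 and 9 with library size alone, where the sign of Val-CAC and Glu-CTC turned. Gly-GCC fell by 1.52 ± 0.14 (adjusted p = 7.82e-07), from 1489 to 519.9 CPM, and Gly-CCC fell by 1.48 ± 0.14. The log2 change was -1.23 for Gln-CTG, -1.07 for Asn-GTT, -0.96 for Lys-CTT, -0.95 for His-GTG, -0.80 for Val-AAC and -0.77 for Lys-TTT. Val-CAC (-0.55) and Glu-CTC (-0.54, adjusted p = 0.0340) were lower by less. Within the same list Glu-TTC (-0.25 ± 0.14, adjusted p = 0.284) and Asp-GTC (0.27 ± 0.18, adjusted p = 0.354) did not pass the test. The family that rose was Leu-AAG (0.55 ± 0.14, adjusted p = 0.0164). In fits that left out 1 library, 20 families were called every time, among them Gly-GCC, Gly-CCC, Lys-CTT, His-GTG, Val-AAC and Lys-TTT, and Leu-AAG, Val-CAC and Glu-CTC were not (highest adjusted p = 0.170, 0.0578 and 0.684).

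**Figure D2:**
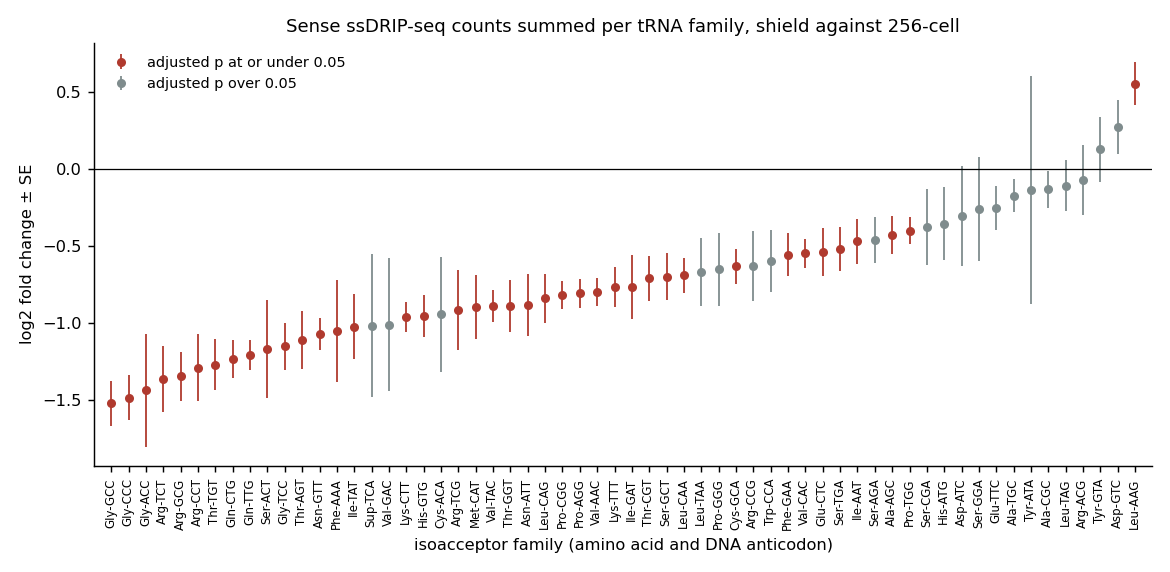
Log2 change of the summed sense ssDRIP-seq count from the 256-cell stage to shield (y axis) for 60 tRNA isoacceptor families (x axis). Points are estimates, bars are ± 1 SE (n = 2 libraries per stage) and red marks adjusted p of 0.05 or less. Gly-GCC and Gly-CCC lie lowest among the 5′ fragment families (-1.52 and -1.48), and with library size alone 12 families were lower and 9 higher, Leu-AAG staying higher and Val-CAC turning sign.

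All 37 mitochondrial genes fell from the 256-cell stage to shield in the sense counts (median -4.83, adjusted p = 0.0174 with an estimated correlation). The log2 change was -5.95 for ATP6, -5.56 for ND5, -5.40 for the cytochrome oxidase gene COX1, -4.53 ± 0.16 for mt-rnr2 and -4.48 ± 0.17 for mt-rnr1. In the mir430 cluster 5 genes rose and 1 fell (2 and 1 by DESeq2, median 0.07, 15 at unadjusted p under 0.05), and with library size alone 36 rose and 0 fell. The gene mir430a-15 rose by 1.11 ± 0.11 and mir430b-5 fell by 0.71 ± 0.18, a call lost with library size alone (-0.11). Summed over the cluster the change was 0.17 ± 0.10 (adjusted p = 0.257).

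From the 256-cell stage to shield, early zygotic genes as a list lay above the other tested features (adjusted p = 0.000978 by camera, 0.0313 by fry, 0.199 with an estimated correlation). Of 43 genes 2 were called higher and 1 lower (2 and 1 by DESeq2, 2 and 1 adjusted over the list alone). That is near the share of all sense features, of which 4.77% were higher and 7.06% lower. For protein-coding genes the shares were 5.88% and 5.14%. Camera also compares the list with tRNA genes (median -0.80), so its p-value alone does not show a rise of the list. The repressor gene ved rose by 3.33 ± 0.27, to 23.3 CPM, and the signalling gene fgf8a by 2.42 ± 0.52. The ventralising factor gene bmp4 fell by 0.74 ± 0.16, a call lost with library size alone. Of 28 maternal genes 6 fell and 0 rose by edgeR (8 at unadjusted p under 0.05, 4 and 0 by DESeq2, 7 adjusted over the list alone, adjusted p = 0.119 by camera), with log2 changes of -3.02 ± 0.64 for btg4, -2.90 ± 0.49 for cth1 and -1.15 ± 0.24 for the germ plasm organiser gene buc. The cyclin genes ccnb1 and ccna1 and the pluripotency gene nanog changed by -1.55, -1.41 and -1.40. Of these genes, buc, ccnb1 and nanog lost their call with library size alone. Only ved and cth1 were called whichever library was left out. The others lost their call without shield replicate 1, and some without shield replicate 2 or a library of another stage.

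Ribosomal protein genes had 5 higher and 1 lower of 84 at shield (1 and 0 by DESeq2, 2 and 0 adjusted over the list alone, adjusted p = 0.00881 by camera, adjusted p = 0.189 by fry, adjusted p = 0.526 with an estimated correlation). The subunit gene rps2 rose by 2.45 ± 0.64 and rpl8 by 1.21, while rpl27a fell by 0.45 and turned to 0.15 with library size alone. The other rises were rpl18 (1.00) and the S6 kinase genes rps6ka4 (0.77) and rps6ka3b (0.45). The Notch ligand gene dld rose by 1.15 ± 0.33 (1 of 25 gastrula genes, 0 by DESeq2, 3 at unadjusted p under 0.05 by edgeR, 0 adjusted over the list alone, adjusted p = 0.0756), the actin gene acta1b by 2.60 ± 0.64 (1 of 24 late tissue genes, 1 by DESeq2, 1 adjusted over the list alone, adjusted p = 0.981) and the succinate dehydrogenase gene sdha by 1.27 ± 0.36 (1 of 16 housekeeping genes, 0 by DESeq2, 5 at unadjusted p under 0.05 by edgeR, 1 adjusted over the list alone, adjusted p = 0.104). Of 16 histone genes h1fx rose by 1.02 ± 0.33 and hist1h2ba fell by 1.26 ± 0.38 (0 by DESeq2, 2 at unadjusted p under 0.05 by edgeR, 1 and 1 adjusted over the list alone, adjusted p = 0.981). Each of these calls was lost in at least 1 fit without a shield library. LOC110439902 was at least 15.5-fold higher at shield, with counts of 46 and 53 against none, and was called in all such fits. Among all sense features 1520 were higher and 2253 lower (791 and 1391 by DESeq2), against 15086 and 638 with library size alone. The total was 2180 without 256-cell replicate 2, 772 without shield replicate 1 and 1098 without shield replicate 2.

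The comparison of shield with sphere asks what changed after activation. The mir430 cluster fell back: 49 of 55 genes were lower and 0 higher by edgeR in the sense counts (47 and 0 by DESeq2, 55 lower adjusted over the list alone, median -1.41, adjusted p = 0.0486 with an estimated correlation; 55 at unadjusted p under 0.05). The gene mir430b-5 (gene5684) fell by 2.23 ± 0.17, mir430c-16 fell by 1.32, and the cluster sum fell by 1.30 ± 0.10 (adjusted p = 5.65e-07), to 2099 ± 30.1 CPM. Mitochondrial genes fell further, 36 of 37 (median -1.36, adjusted p = 0.0860 with an estimated correlation), with changes of -1.80 ± 0.15 for COX2 and -1.31 ± 0.14 for mt-rnr2. Of the nuclear tRNA genes 25 fell and 0 rose by edgeR (1248 at unadjusted p under 0.05, 8 and 0 by DESeq2, median -0.60), with 1 lower and 0 higher adjusted over the list alone and adjusted p = 0.199 with an estimated correlation. In the 10 families known for 5′ fragments 8 genes fell and 0 rose by edgeR (465 at unadjusted p under 0.05, 2 by DESeq2, 0 adjusted over the list alone, adjusted p = 0.199 with an estimated correlation). By fry, adjusted p was 0.0858 for all nuclear tRNA genes and 0.0573 for these families. The tRNA total was 2 without sphere replicate 1 or without shield replicate 1, 11 without sphere replicate 2 and 118 without 256-cell replicate 1. As family sums 27 of 60 fell and 0 rose by edgeR (22 with library size alone), led by Thr-TGT (-1.15 ± 0.16), and Thr-TGT, Thr-CGT, Glu-TTC, Gly-GCC, Asn-GTT and Lys-CTT were called whichever library was left out.

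Rises from sphere to shield were few in the fit on all 6 libraries (35 features), against 95 in the fit on these 2 stages only. The early zygotic gene ved rose by 1.24 ± 0.20 (1 of 43, 1 by DESeq2, 1 adjusted over the list alone), and its list had adjusted p = 0.00635, and adjusted p = 0.231 with an estimated correlation, its call being lost without sphere replicate 2 or shield replicate 1. Fry gave the early zygotic list adjusted p = 0.0869. The plakin gene eppk1 (gene30053) rose by 1.36 ± 0.15, ccdc149a (gene17276) by 1.31 ± 0.10, from 149 to 369 CPM, the adhesion gene cntn2 (gene21448) by 0.97 ± 0.12 and the kinase gene raf1a (gene34682) by 0.94 ± 0.12. Housekeeping genes as a list lay above the other tested features (adjusted p = 0.000162 by camera, 0.0409 by fry, 0.173 with an estimated correlation). By edgeR and DESeq2 0 of 16 were called over all genes, with 6 at unadjusted p under 0.05 and 2 adjusted over the list alone. Ribosomal protein genes did so by camera (adjusted p = 0.000365), but not by fry (adjusted p = 0.214) or with an estimated correlation (adjusted p = 0.447). Of these, 0 of 84 were called by edgeR and DESeq2, 8 at unadjusted p under 0.05 and 0 adjusted over the list alone. The camera call was lost without shield replicate 1. The median change was -0.60 for nuclear tRNA genes and 0.06 for protein-coding genes, so a list can lie above the other features without rising itself. No maternal, gastrula, late tissue or histone gene was called by edgeR or DESeq2 (0 of 28, 25, 24 and 16, also adjusted over the list alone; 1, 3, 3 and 0 at unadjusted p under 0.05). Among all sense features 35 were higher and 272 lower (27 and 211 by DESeq2). The total was 104 without shield replicate 1, 177 without shield replicate 2, 134 without sphere replicate 1, 616 without 256-cell replicate 1 and 592 without 256-cell replicate 2.

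Antisense counts were compared in the same way. All 37 mitochondrial genes fell from the 256-cell stage to sphere (median -4.06) and to shield (median -4.85; adjusted p = 0.0141 with an estimated correlation in both). ND6, the complex I gene on the light strand, fell by 5.75 ± 0.12 to shield, from 12599 to 234 CPM. From sphere to shield 22 fell and 1 rose, the tRNA gene trnH by 1.91 ± 0.28 (median -0.92, adjusted p = 0.105 with an estimated correlation). The rise of trnH was lost without sphere replicate 1 or 2. The antisense counts of mir430 showed 1 rise at sphere (mir430a-13, 0.46 ± 0.12) of 54 tested, 4 rises at shield against the 256-cell stage, and 2 falls from sphere to shield. DESeq2 called 1, 3 and 0 of them, and 12, 13 and 9 genes were at unadjusted p under 0.05 by edgeR. At sphere the list had adjusted p = 0.00125 by camera, a call lost without sphere replicate 2, and adjusted p = 0.526 with an estimated correlation. The cluster sum changed by 0.21 (adjusted p = 0.0708) to sphere and by 0.22 (adjusted p = 0.0381) to shield.

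Antisense counts of nuclear tRNA genes fell from the 256-cell stage to shield, with 277 lower and 13 higher of 1325 (139 and 5 by DESeq2, 345 and 17 adjusted over the list alone, median -0.87, adjusted p = 2.05e-11, adjusted p = 0.0441 by fry, adjusted p = 0.280 with an estimated correlation). To sphere 96 were lower and 5 higher (7 and 1 by DESeq2, 113 and 7 adjusted over the list alone, adjusted p = 0.000167, adjusted p = 0.447 with an estimated correlation and 0.244 without 256-cell replicate 2). In the 10 families known for 5′ fragments 102 genes fell and 1 rose at shield (39 and 0 by DESeq2, 142 and 6 adjusted over the list alone, adjusted p = 0.351 with an estimated correlation), and 21 fell and 3 rose at sphere (0 by DESeq2, 140 at unadjusted p under 0.05 by edgeR, 32 and 6 adjusted over the list alone, adjusted p = 0.450 with an estimated correlation and 0.225 without 256-cell replicate 2). The family sum of Leu-CAG fell by 1.92 ± 0.10 to shield (adjusted p = 1.33e-13), from 556 to 147 CPM, with Gly-GCC (-1.91 ± 0.14) and Gly-CCC (-1.90 ± 0.15) close to it, and Gly-TCC rose by 0.80 ± 0.14. Of 56 families 28 fell and 1 rose. From sphere to shield 1 tRNA gene fell by edgeR and 0 by DESeq2 (140 at unadjusted p under 0.05, 1 adjusted over the list alone), with adjusted p = 0.280 with an estimated correlation. In the 10 families known for 5′ fragments 0 genes were called by edgeR and DESeq2 (43 at unadjusted p under 0.05, 0 adjusted over the list alone, adjusted p = 0.409 with an estimated correlation). The number of lower tRNA genes at shield was 123 without 256-cell replicate 2, 70 without shield replicate 1 and 115 without shield replicate 2.

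Among other genes on the antisense strand, ved rose by 3.72 ± 0.70 from the 256-cell stage to shield and the apolipoprotein gene apoeb by 3.26 ± 0.72 (2 of 35 early zygotic genes, 2 by DESeq2, 2 adjusted over the list alone). At sphere ved, apoeb and tfap2a rose (3 of 35, 0 by DESeq2, 7 at unadjusted p under 0.05 by edgeR, 4 adjusted over the list alone). The germ plasm gene buc rose by 1.18 ± 0.32 and the TGF-beta family gene gdf3 fell by 0.76 ± 0.17 at shield (1 and 1 of 31 maternal genes, 1 and 1 by DESeq2, 5 and 2 adjusted over the list alone), and pou5f3 rose at sphere (0 by DESeq2, 11 at unadjusted p under 0.05 by edgeR, 1 adjusted over the list alone). Ribosomal protein genes had 4 rises and 1 fall of 80 at shield (1 and 0 by DESeq2, 1 and 0 adjusted over the list alone), and 2 rises at sphere (2 by DESeq2, 2 adjusted over the list alone). At shield, szl fell in the gastrula list (1 of 23, 0 adjusted over the list alone), pmela rose and fabp10a fell in the late tissue list (1 and 1 of 25, 1 and 0 adjusted over the list alone), eef1a1l1 and polr2a rose in the housekeeping list (2 of 17, 3 adjusted over the list alone) and h2afy rose in the histone list (1 of 11, 0 adjusted over the list alone). Of these 4 lists DESeq2 called 1 late tissue gene higher and 0 in the others, and at unadjusted p under 0.05 edgeR had 2, 3, 4 and 2 genes. At sphere 2 late tissue genes of 25 rose (acta1b and pmela, 2 and 1 adjusted over the list alone), as did polr2a of the 17 housekeeping genes (1 adjusted over the list alone), with 0 of either list by DESeq2 and 8 and 4 at unadjusted p under 0.05 by edgeR. No gastrula or histone gene was called there by edgeR or DESeq2 (0 of 23 and 11, also adjusted over the list alone; 4 and 3 at unadjusted p under 0.05). From sphere to shield the complement protease gene c1r (gene26944) rose by 1.69 ± 0.13, from 50.0 to 162 CPM, and zgc:153920 (gene22548) by 1.67 ± 0.15. None of the ribosomal protein, early zygotic, maternal, late tissue, histone, housekeeping or gastrula genes was called by edgeR or DESeq2 between sphere and shield, also adjusted over the list alone (5, 3, 4, 2, 1, 1 and 0 at unadjusted p under 0.05).

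Antisense totals were 603 higher and 1165 lower at sphere against the 256-cell stage (260 and 738 by DESeq2), 1570 and 2242 at shield (775 and 1471 by DESeq2) and 35 and 84 from sphere to shield (25 and 59 by DESeq2). With library size alone the first became 2277 and 599, and the shield comparison 4239 and 1180. The sphere total was 383 without sphere replicate 1 and 1053 without 256-cell replicate 1. The shield total was 1334 without shield replicate 1 and 1304 without shield replicate 2, and that from sphere to shield 45 without sphere replicate 1 and 63 without shield replicate 1. Apart from ved at shield, each antisense call named above in the early zygotic to housekeeping lists was lost in at least 1 fit without a sphere, shield or 256-cell library.

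The ratio of sense to antisense counts asks which strand carried the signal at each stage. Nuclear tRNA genes carried it on the sense strand: the ratio of their summed counts was 4.17 ± 0.190 at the 256-cell stage, 5.27 ± 0.150 at sphere and 4.66 ± 0.242 at shield (SD, n = 2). The ratio of the other nuclear features was 0.839 ± 0.00959, 0.868 ± 0.0121 and 0.901 ± 0.00436. Of 5736 tRNA genes tested, 3740, 4484 and 4015 were higher on the sense strand at the 3 stages and 46, 92 and 87 on the antisense strand (3851, 4604 and 4182 against 50, 102 and 100.0 adjusted over the list alone). Their median log2 ratios were 2.78, 3.21 and 2.91, with adjusted p = 0.199, 0.0141 and 0.0141 with an estimated correlation. In the 10 families known for 5′ fragments 1311, 1498 and 1375 of 1793 genes were higher on the sense strand, and 8, 30 and 20 on the antisense strand (1366, 1548 and 1449 against 9, 32 and 28 adjusted over the list alone), with adjusted p = 0.179, 0.0176 and 0.0180 with an estimated correlation. Examples are trnas-aga gene31042, at least 42.7-fold higher on the sense strand at the 256-cell stage (128 counts against none), trnal-aag gene12116, at least 110.3-fold at sphere, and trnak-uuu gene7613, at least 65.3-fold at shield.

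Mitochondrial genes split by their coding strand. The 28 genes transcribed from the heavy strand were all higher on the sense strand at each stage, with median log2 ratios of 5.05 at the 256-cell stage and 5.45 at sphere. Of the 9 light-strand genes (8 tRNAs and ND6), 8 were higher on the antisense strand at each stage, with medians of -2.74, -2.42 and -2.84. The other, trnY, did not pass at the 256-cell stage and was higher on the sense strand at sphere (0.90) and shield (0.58). This grouping was chosen after the values were seen. As a list of 37 they had adjusted p = 0.0936, 0.199965 and 0.199 with an estimated correlation. Relative to the annotated strands, the excess lay on the same strand of the mitochondrial DNA in both sets, apart from trnY. The mir430 genes were higher on the sense strand in 34, 53 and 36 of 55 cases and on the antisense strand in 4, 0 and 7 by edgeR (35, 53 and 38 against 4, 0 and 7 adjusted over the list alone; at sphere 51 and 0 by DESeq2 and 53 in all at unadjusted p under 0.05). The ratio of their summed counts was 1.66 ± 0.205, 4.08 ± 0.0261 and 1.67 ± 0.133 at the 3 stages, and their lists had adjusted p = 0.485, 0.207 and 0.447 with an estimated correlation.

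Of 33 maternal genes 11, 16 and 18 were higher on the antisense strand and 5, 1 and 1 on the sense strand (11, 16 and 18 against 5, 1 and 2 adjusted over the list alone). Among all protein-coding genes 32.9%, 33.9% and 28.1% were higher on the antisense strand and 22.1%, 23.7% and 21.7% on the sense strand. At the 256-cell stage the antisense count of the maternal list lay near that share. The camera tests of this list had adjusted p = 0.167, 0.00131 and 0.000236, with adjusted p = 0.233 at sphere and adjusted p = 0.199 at shield with an estimated correlation. They compare it with all other features, among them the tRNA genes, most of which were higher on the sense strand. Housekeeping genes had 8 of 17 higher on the antisense strand and 1 on the sense strand at sphere (8 and 1 adjusted over the list alone, adjusted p = 0.0293 by camera, a call lost without sphere replicate 2, adjusted p = 0.351 with an estimated correlation). At the 256-cell stage and at shield these counts were 8 and 2 (adjusted p = 0.104) and 7 and 3 (adjusted p = 0.165). The forkhead gene foxd1 (gene13574) was at least 28.7-fold higher on the antisense strand at sphere and lepb, a leptin gene, at least 17.3-fold at the 256-cell stage. Ribosomal protein, histone, early zygotic, gastrula and late tissue genes did not pass by camera at any stage (adjusted p between 0.298 and 0.995). In total 9682, 10861 and 9843 features were higher on the sense strand and 8855, 9157 and 7556 on the antisense strand at the 256-cell, sphere and shield stages. At shield the total was 11494 without shield replicate 1 and 10375 without shield replicate 2.

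A change of this ratio between the 256-cell stage and shield was tested as an interaction. It rose for 2409 features and fell for 1004 (527 and 190 by DESeq2), against 1680 and 1277 with separate scaling of the strand columns. Of the 5736 nuclear tRNA genes 103 rose and 54 fell (18 and 15 by DESeq2, 45 and 27 adjusted over the list alone, adjusted p = 0.298), and 34 and 6 in the 10 families known for 5′ fragments (8 and 0 by DESeq2, 13 and 0 adjusted over the list alone, adjusted p = 0.981). Maternal genes had 7 falls and 0 rises of 33 by edgeR (2 and 0 by DESeq2, 13 at unadjusted p under 0.05, 9 and 1 adjusted over the list alone). Their list had adjusted p = 0.0357 by camera, a call lost without sphere replicate 1, and adjusted p = 0.351 with an estimated correlation. The mir430 list had 2 rises and 1 fall (1 and 0 by DESeq2, 1 and 0 adjusted over the list alone, adjusted p = 0.411) and the mitochondrial genome 11 and 10 (5 and 4 by DESeq2). Ribosomal protein genes had 4 and 2, early zygotic genes 1 and 2 and housekeeping genes 1 and 0, with the same counts adjusted over the list alone, 0 in each by DESeq2 and 14, 7 and 2 at unadjusted p under 0.05 by edgeR. No histone, gastrula or late tissue gene passed by edgeR or DESeq2 (0 of 16, 25 and 25, also adjusted over the list alone; 1, 4 and 4 at unadjusted p under 0.05). For LOC110439902 the sense counts went from 0 and 0 to 46 and 53 while the antisense counts went from 12 and 9 to 42 and 29. The total was 1797 without 256-cell replicate 2, 1167 without shield replicate 1 and 1396 without shield replicate 2.

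Small RNA libraries ask which tRNA fragments are present from egg to 24 hpf. With 1 library per stage, no difference could be tested against the spread between embryos. Fragments of Gly-GCC were the most abundant family in each library, with 19590 RPM in the egg (95% interval 19518 to 19663), 17681 at the 256-cell stage, 30136 at shield (30041 to 30230.4) and 17261 at 24 hpf. That was 34.6%, 40.5%, 36.1% and 25.9% of the summed fragments. Asp-GTC, the largest riser in RPM after Gly-GCC, had 5422 RPM in the egg, 3278 at the 256-cell stage, 11243 at shield and 8468 at 24 hpf, a 3.43-fold higher value at shield than at the 256-cell stage, and 7.51% against 13.5% of the summed fragments. Glu-TTC had 8109, 4866, 9671 and 9651 RPM in these libraries. Glu-CTC was highest in the egg, at 4338 RPM against 1595 at the 256-cell stage. The most abundant fragment was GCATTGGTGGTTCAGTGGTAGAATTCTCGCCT of Gly-GCC, 32 nt long, with 3262 RPM in the egg and 4849 at shield. In His-GTG it was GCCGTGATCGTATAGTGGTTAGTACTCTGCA, 31 nt long, with 1478 RPM in the egg and 4177 at 24 hpf.

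Fragments from the 5′ end made up 65.8% of the summed RPM in the egg, 75.1% at shield and 59.7% at 24 hpf, and those from the 3′ end 14.5%, 10.7% and 16.8%. In Gly-GCC, 5′ fragments of at least 30 nt made up 82.5% at shield and in His-GTG 88.8%, against 6.93% in Glu-CTC and 0.104% in Met-CAT. Tyr-GTA went from 0.363% in the egg to 44.5% at shield. Among 37 families of at least 100 RPM, 8 were 2-fold or more higher and 4 lower at shield than in the egg. Scaled as shares of the summed fragments, 4 were higher and 8 lower. Tyr-GTA was 4.97-fold higher at shield than in the egg, Ser-AGA 3.84-fold and Val-AAC 3.23-fold, and Arg-CCT went from 781 to 189 RPM. From shield to 24 hpf 8 were higher and 3 lower, and as shares 12 and 1. Val-TAC was 4.21-fold and Ala-AGC 3.89-fold higher at 24 hpf, while Val-AAC went from 3511 to 1346 RPM and Ser-AGA from 1240 to 539. As shares, Gly-GCC changed by 0.06 on the log2 scale from egg to shield against 0.62 in RPM, and Val-AAC by 1.13 against 1.69.

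**Figure D3:**
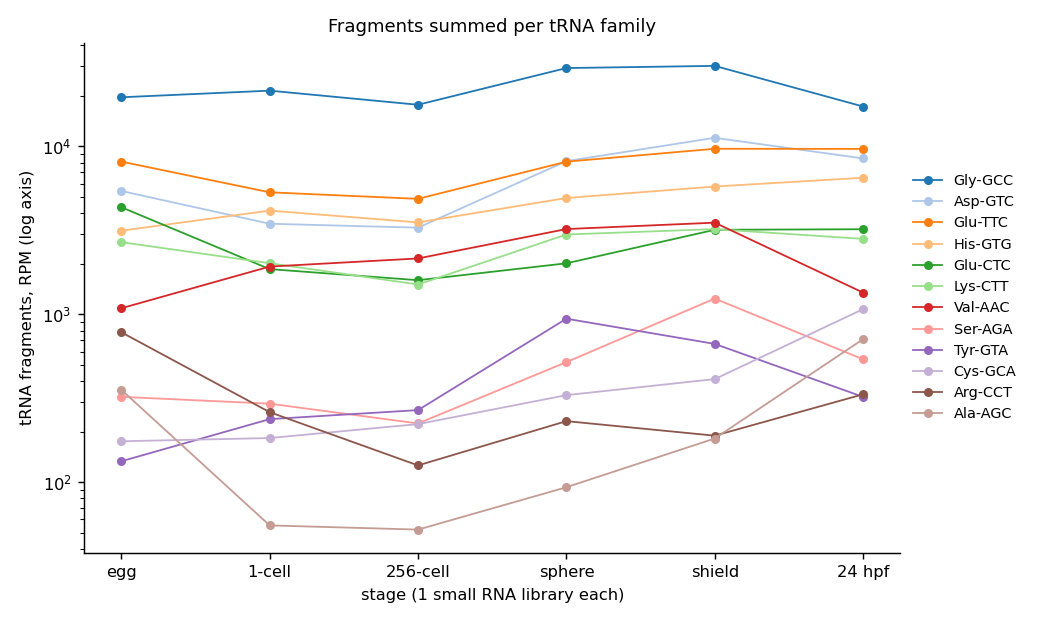
Abundance of tRNA fragments (y axis, RPM, log scale) in 12 isoacceptor families at 6 stages from egg to 24 hpf (x axis), 1 library per stage. Gly-GCC lies highest at each stage (19590 RPM in the egg, 30136 at shield), and Tyr-GTA went from 133 in the egg to 941 at sphere.

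The study asks whether 5′ tRNA fragments bear on R-loops at the tRNA genes they come from, so fragment levels were set against ssDRIP-seq counts across 54 families. Families are not independent replicates, since they share genes and fragments of like sequence. With 6 relations computed, families with more 5′ fragments of at least 30 nt had higher mean sense counts per gene at all 3 stages. At the 256-cell stage r was 0.338 (permutation p = 0.0124, adjusted p = 0.0457) and rho 0.341 (adjusted p = 0.0251). At sphere r was 0.295 (permutation p = 0.0305, adjusted p = 0.0457) and rho 0.313 (adjusted p = 0.0332). At shield r was 0.329 (permutation p = 0.0158, adjusted p = 0.0457) and rho 0.354 (adjusted p = 0.0251). Without Gly-GCC and Glu-TTC, the families farthest from the median, r was 0.376, 0.328 and 0.379. Antisense counts gave r = 0.305 at the 256-cell stage (permutation p = 0.0241, adjusted p = 0.0457; rho 0.401, adjusted p = 0.0182), 0.178 at sphere (permutation p = 0.197, adjusted p = 0.197; rho 0.247, adjusted p = 0.0717) and 0.197 at shield (permutation p = 0.155, adjusted p = 0.186; rho 0.261, adjusted p = 0.0685). Without the same 2 families these were 0.301, 0.185 and 0.228. The family means cover all genes without the count filter. On the antisense strand 1325 of 7977 nuclear tRNA genes passed that filter, so these means include many genes near the prior count. With all fragments of a family in place of long 5′ fragments, r lay between 0.0734 and 0.287 and none passed. With egg fragments in place of those of the same stage, the sense relations at sphere and shield did not pass for r (adjusted p = 0.0760 and 0.0609; rho adjusted p = 0.0402 and 0.0298), and the antisense ones did (adjusted p = 0.0342 for both). Without sphere replicate 1 the sense relation at sphere had adjusted p = 0.0641.

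**Figure D4:**
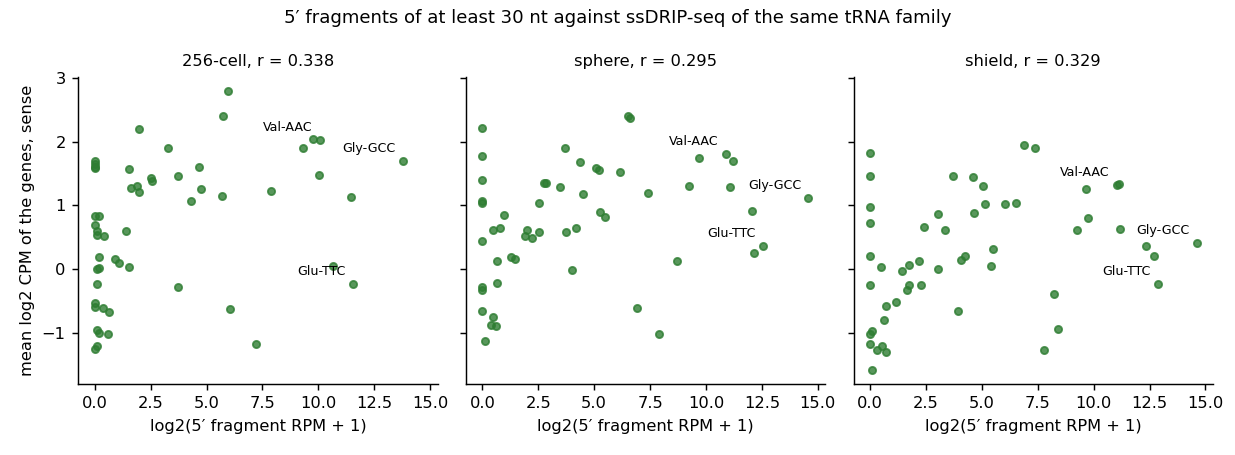
5′ fragments of at least 30 nt per tRNA family (x axis, log2 of RPM + 1) against the mean sense ssDRIP-seq count of its genes (y axis, log2 CPM) at the 256-cell, sphere and shield stages, with 1 point per family (54). Pearson's r was 0.338, 0.295 and 0.329, and the points scatter widely around the trend.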

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

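The tests of scaling, of dilution, of recovery on both strands, of reads between mir430 or tRNA copies, of 256-cell replicate 2 and of a loss on both strands were chosen only after the result was seen. The comparison of tRNA genes with features of matched counts was set after the tRNA fall was seen but before its own result was. The test of the change in the sense to antisense ratio from the 256-cell stage to shield was planned.

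Mitochondrial R-loop counts fell by a median of 4.83 on the log2 scale from the 256-cell stage to shield. The choice among 4 scalings (TMM, library size alone, DESeq2 size factors and the authors' own) does not account for this, since the median stayed at -4.22 or lower. All but library size gave nearly the same value (-4.83, -4.82 and -4.82), so they are hardly separate checks. Without an outside reference, the values show a fall relative to the nuclear features. Fewer mitochondrial genomes per nuclear genome as cells divide would move all 37 genes alike, if every count came from mitochondrial DNA. Scaled on the mitochondrial genes themselves, 20 of them still changed, from -1.58 for trnE and -1.22 for ATP6 to 0.49 for trnR. Only under that condition do these values argue against dilution as the whole cause. Background reads of other origin were not measured, so the test cannot exclude it. For the common part of the fall, dilution and fewer hybrids per genome both stay open, as no input DNA library was analysed here. Antisense counts fell by a median of 4.85. The sense to antisense ratio changed by a median of 0.075, with 11 genes higher and 10 lower. Dilution would lower both strands alike, and fewer hybrids could too, so these values do not separate them.

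The mir430 sense counts rose from the 256-cell stage to sphere and fell back by shield. The choice among the same 4 scalings does not account for the rise, as the lowest median change to sphere among them was 1.47. All but library size again gave nearly the same value. More DNA of the cluster recovered on both strands would leave the ratio of the strands unchanged, but 38 of 55 genes had a higher sense to antisense ratio at sphere. Reads moving between near-identical copies would leave the cluster sum unchanged, but it rose by 1.46 on the log2 scale. What formed the excess on the sense strand stays open, as neither RNA of the cluster nor the RNase H control was analysed here.

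Sense counts of nuclear tRNA genes were lower at shield than at the 256-cell stage with TMM scaling (median -0.80). With library size alone the median was -0.20, and 12 families were lower and 9 higher, but all features then shifted by 0.60 as the mitochondrial share shrank. With the library size of nuclear counts, where all features shifted by 0.045, the median was -0.76 and 35 families were lower and 1 higher. A scaling moves all features of a library alike, so it cannot change the place of tRNA genes below other nuclear features. Whether tRNA counts fell in absolute terms depends on the scaling, and these values do not decide it. Low counts do not account for the place of these genes below other features, since features of matched counts had a median 0.908 higher, nor does 256-cell replicate 2 alone account for the families, as 23 were lower without it with TMM. Reads moving between copies of a family would leave the family sums unchanged, but 39 of 60 fell with TMM. A loss on both strands alike is undecided. Over 1189 genes the antisense median differed from the sense median by -0.039 with TMM, which scales each strand on its own. With library size alone the difference was -0.454. The ratio of the strands changed by a median of 0.205 in these genes, 0.044 over all tRNA genes tested for it and 0.096 over all features. Such a loss, reads shared between families of like sequence and the stages themselves stay open.

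The sense to antisense ratio changed between the 256-cell stage and shield for 3413 features by a test of the difference itself. The largest fitted rises were 8.16 for trnal-gag gene7934, 7.54 for LOC110439902, 7.24 for ccr8.1, 7.20 for trnai-aau gene11267, 6.67 for trnap-agg gene30533 and 6.64 for lepb on the log2 scale. Large fitted falls were -6.99 for trnal-caa gene27985, -6.48 for trnap-cgg gene10079, -6.46 for si:dkey-23a13.1, -6.38 for LOC108179808 and -6.37 for trnak-cuu gene6884. Each had 0 counts on 1 strand in both libraries of a stage, so these fitted values depend on the prior count and are no bounds. Only the calls of LOC110439902 and trnai-aau gene11267 held whichever library was left out.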

How the results depend on the processing

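The fits without mitochondrial genes and the exact binomial test of small RNA libraries were chosen only after seeing the data. For the changes below the cause was not tested unless stated. With library size alone, calls were 14327 (sense) and 2876 (antisense) for sphere against the 256-cell stage and 15724 for shield sense, following the shift of all features. Fits on only the stages compared had fewer libraries to estimate the spread. Calls went from 1222 to 744 (sense sphere against 256-cell) and from 1768 to 1131 (antisense sphere). For sense shield against sphere they rose from 307 to 533, which fewer libraries do not explain. The DESeq2 Wald test gave 2182 (sense shield), 998 and 2246 (antisense sphere and shield against the 256-cell stage) and 717 for the change of the strand ratio. Without a filter, antisense shield against sphere had 224 calls. With an estimated correlation 9 of the 110 list tests passed, and 33 by fry (41 with the preset). With each library left out, which assumes that the lone library of a stage varies like the others, calls ranged from 448 to 1208, 772 to 3746 and 104 to 616 (sense sphere and shield against the 256-cell stage, and shield against sphere), and from 383 to 1348, 1304 to 3862 and 45 to 176 (antisense). For the strand ratio the ranges were 12494 to 18284, 14536 to 21063 and 10375 to 18417 at the 3 stages and 1167 to 3157 for its change, for lists 38 to 47 and for the 6 family correlations 3 to 4. With a replicate block for the pairing of the titles, calls were 1068, 3454 and 299 (sense), 1562, 3550 and 113 (antisense) and 41 for lists. Without mitochondrial genes they were 1235, 3885 and 272 (sense) and 1795, 3862 and 95 (antisense). Of the family correlations, 4 passed with the main choice, 0 with all fragments, 4 with egg fragments and 6 with sums over genes, where the number of genes enters. The 4 with egg fragments were others: the sense relations at sphere and shield were lost (adjusted p = 0.0760 and 0.0609) and the antisense ones passed at both (adjusted p = 0.0342). Directions turned for rpl27a at shield (0.15 with library size alone) and for the late tissue list, which fry put on the sense strand at sphere (adjusted p = 0.0386) and shield (adjusted p = 0.0219). As shares of all fragments, the changes from egg to shield turned for Glu-TTC (-0.31), Lys-CTT (-0.30), Pro-AGG (-0.43), Trp-CCA (-0.37) and Val-CAC (-0.18), and from shield to 24 hpf for Glu-TTC (0.32), Lys-CTT (0.13), Met-CAT (0.20) and Val-CAC (0.032). Glu-CTC turned to -0.027 with the filter of 1 RPM. The exact binomial test called 45 families from egg to shield and 47 from shield to 24 hpf. Among the named features, each counted once per comparison, 38 calls were lost by DESeq2 and 208 held. With library size alone 12 were lost, 1 turned direction and 331 held. DESeq2 covered fewer of these results, so its counts are not shares of all of them.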

Other observations

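The relation of changes across tRNA families in this part was a test chosen only after the data were seen, as were the features singled out here.

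The feature zgc:158463 (gene12823), the 1 nuclear feature of the ribosomal RNA class tested, fell in the sense counts by 1.37 ± 0.14 from the 256-cell stage to sphere and by 1.68 ± 0.14 to shield (SE, n = 2 per stage; adjusted p = 1.19e-07 by edgeR). Its log2 ratio of sense to antisense counts stayed at 3.07, 3.09 and 3.06 at the 3 stages. Among 23965 protein-coding genes tested in the sense counts, 1409 were higher and 1232 lower at shield than at the 256-cell stage, and among 2132 long non-coding RNA genes 70 were higher and 116 lower. Library size alone shifted the median of all sense features by 0.60 between these stages, so such splits depend on the scaling.

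Fragment lengths moved with the stage. Fragments of 32 nt held 16.5% of the summed RPM in the egg, 23.5% at the 1-cell stage, 16.4% at shield and 11.1% at 24 hpf, and those of 33 nt 15.5%, 18.8%, 23.5% and 13.9%. A terminal mismatching A was carried by 10.7% of the summed RPM at shield and 14.6% at 24 hpf. These libraries had no replicates.

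If long 5′ fragments preserve R-loops at the genes they come from, families whose fragments rose more from the 256-cell stage to shield may have kept more of their sense ssDRIP-seq count. Across 54 families, which are not independent replicates, the changes correlated at r = 0.393 (permutation p = 0.00297, bootstrap interval 0.0745 to 0.615), with rho 0.233 (permutation p = 0.0914). Without Tyr-GTA and Leu-AAG, the families farthest from the median, r was 0.182 (permutation p = 0.198), so the relation rests on those families. The long 5′ fragments of Tyr-GTA went from 0.567 to 296 RPM and those of Leu-AAG from 1.63 to 90.1, and their mean sense changes were 0.28 and 0.45 on the log2 scale. The test leaves the hypothesis undecided.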
